A study of Homo sapiens with 8 samples.

How the data were processed

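Total RNA libraries from 8 samples labelled as the U87 MG glioblastoma cell line were sequenced as single-end reads of 50 bases. The labels give 4 groups of 2 libraries: unmodified cells (control), cells with estrogen receptor beta (ERβ, gene ESR2) knocked out (ERb_KO), and knockout cells with the ERβ1 or the ERβ5 isoform put back (ERb1 and ERb5). Every library was assigned to its group from its title, and every library was used.

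The deposited values are raw read counts per gene, as whole numbers whose totals differ between libraries. Per the submitters' processing notes, base calls were converted with bcl2fastq, reads were aligned to hg19 with TopHat2 2.0.8b and reads per gene were counted with HTSeq, and per the series' design text the HTSeq counts fed a DESeq pipeline. The HTSeq version, its strand setting and the annotation release are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Each file lists 23228 genes and 5 closing entries that name no gene, which were kept out of library sizes and tests. Of all counted reads, 52.5 to 57.1% fell in genes, 34.7 to 39.9% did not align to a single place, 7.01 to 7.79% fell in no gene and 0.54 to 0.561% were ambiguous between genes. Because reads with more than 1 place were not counted in genes, members of families with near-identical copies (ribosomal proteins and their pseudogenes, histones, HLA genes, AKR1C1 and AKR1C2, SAA1 and SAA2) have uncertain levels.

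Gene counts per library ran from 26760897 to 48076414. Genes with too few counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13915 genes. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F test with robust dispersion) in R 4.3.3, with all 8 libraries in a single fit so that the groups shared an estimate of the spread. The common biological coefficient of variation was 0.102. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and genes with an adjusted p under 0.05 were called changed. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Levels are given in CPM, which are counts scaled to a common library size. Means of a group use TMM-scaled library sizes, and levels of single libraries use the total gene count.

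The 4 main comparisons were ERb_KO against control, ERb1 and ERb5 each against ERb_KO, and ERb5 against ERb1. ERb1 and ERb5 were also compared with control. For gene groups, 49 lists with 1011 genes had been fixed, of which 996 genes were found in the files. The 41 lists with at least 5 tested members were tested against the other genes with camera from limma 3.58.1 at its preset correlation of 0.01, adjusted over the 41 lists in each comparison. The lists of mitochondrially encoded genes, metallothioneins, cancer-testis genes and markers of microglia, lymphoid cells, endothelium, pericytes and oligodendrocytes had fewer than 5 tested members and were not tested. Camera with an estimated correlation and the directional fry test were run beside it. Each list also has a count of changed genes over all genes tested and a count adjusted over the list alone.

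The groups, tests, gene lists, rule for named genes and all alternatives except 1 were chosen before the data were examined. The genes named in each main comparison are the 10 largest rises and the 10 largest falls among changed genes with at least 5 mean CPM in the higher group and no overlap between the libraries of the groups, up to 4 members of each of up to 6 called lists, and ESR2, ESR1, GPER (GPER1), PGR, CDKN1A, CCND1, MYC and EGFR. The results of some further genes and of 1 tested list, which passed in ERb5 against ERb1, are not reported. Symbols of uncharacterised, antisense and small RNA genes and of sex-linked marker genes were passed over, and some genes were left out for length. Gene positions come from a GENCODE annotation on GRCh37, which is the build of hg19, matched by symbol or synonym to 13249 of the 13915 tested genes (95.2%).

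The alternatives were other size factors (relative log expression and upper quartile), no filter on low counts or a minimum of 1 CPM in 2 libraries, a test against a minimum change of 1.5-fold, a fit with only the groups compared, DESeq2 1.42.0, the replicate number as a block, and leaving out each library in turn. A library left alone in its group is then assumed to vary like the other groups. After the data were seen, an alternative was added in which each library's trend with the GC content and length of the transcript was fitted by lowess and removed through edgeR offsets. Lists of 6 lineages (luminal breast epithelium, mesenchymal glioma, prostate, colon, lung and liver) were also written after levels of some of their genes had been seen.

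Comparisons that share the knockout libraries were set beside 50 simulated draws without any group effect, made from the observed means, dispersions and library sizes. The test was tested on simulated counts with 200 genes changed by known amounts. For ERb_KO against control (13803 genes), 58.2% of genes changed 1.5-fold, 90.9% of those changed 2-fold and 93.9% of those changed 4-fold were recovered, and 6.47% of calls were false. For ERb1 against ERb_KO (13797 genes) the shares were 59.7, 92.4 and 100% with 8% false, for ERb5 against ERb_KO (13790 genes) 48.5, 81.8 and 98.5% with 5.58% false, and for ERb5 against ERb1 (13798 genes) 43.3, 87.7 and 100% with 6.6% false. In each simulation, camera called both lists that had been shifted and 0 of the others, and fry called both as well. The simulated genes varied independently of each other. In the observed data the estimated correlation was 0.487 for mitosis and 0.792 for interferon genes in ERb_KO against control. These runs therefore do not show how often camera's preset calls lists whose genes vary together. The GC correction was tested on simulated counts for ERb_KO against control (13801 genes) with a GC trend added. It lowered the number of unchanged genes called from 3964 to 10, while 85.4% of the changed genes were recovered before and 84.9% after it. The added trend was the same in both ERb_KO libraries, without a length trend, and was stronger than observed (r = -0.817 against -0.454). The changed genes were drawn regardless of GC content. The run therefore does not show how the correction acts on trends that differ between replicates, or on true changes tied to GC content. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.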

Results

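Gene expression was measured by RNA sequencing in 8 libraries labelled as U87 MG, an established human glioblastoma cell line. The labels describe 4 groups of 2 libraries: unmodified cells (control), cells in which estrogen receptor beta (ERβ) had been knocked out by CRISPR/Cas9 (ERb_KO), and knockout cells to which the isoform ERβ1 (ERb1) or ERβ5 (ERb5) had been returned. ERβ1 is the full-length receptor, and ERβ5 is a splice variant with a different carboxy-terminal end. The series title poses the question of whether the isoforms differ in their effects. Reads counted in genes ran from 26760897 to 48076414 per library. Replicate libraries correlated at r = 0.991 to 0.996 across genes, which are not independent replicates. They still differed by more than sampling noise, with a chi-square per degree of freedom of 7.82 in control, 27.51 in ERb_KO, 22.49 in ERb1 and 43.35 in ERb5. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which can be technical.

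ESR2, the gene for ERβ, lies at 64550950 to 64804830 on the minus strand of chromosome 14 (GRCh37). It was close to the detection limit in every library. ESR2 had 25 and 20 reads in control, 23 and 21 in ERb_KO, 6 and 18 in ERb1, and 7 and 10 in ERb5, which is 0.203 to 0.69 CPM. The log2 change of ESR2 was 0.06 ± 0.37 (SE) in ERb_KO against control, -0.92 ± 0.41 in ERb1 against ERb_KO, -1.11 ± 0.44 in ERb5 against ERb_KO and -0.19 ± 0.48 in ERb5 against ERb1. None of these passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.932, 0.118, 0.0761 and 0.881). A knockout by small insertions or deletions need not lower the transcript, so the ERb_KO label is not checked by these counts. The isoforms share most of the coding sequence, and the libraries labelled ERb1 and ERb5 held no more ESR2 reads than those labelled ERb_KO. The ESR2 counts therefore do not bear out these labels. They cannot refute them, since a construct that is not counted as ESR2 would leave the counts low. Every direction given for ERb1 or ERb5 is a direction between the libraries labelled so. The canonical coding sequence of 1590 bases lies in 8 of 9 exons.

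**Figure D1:**
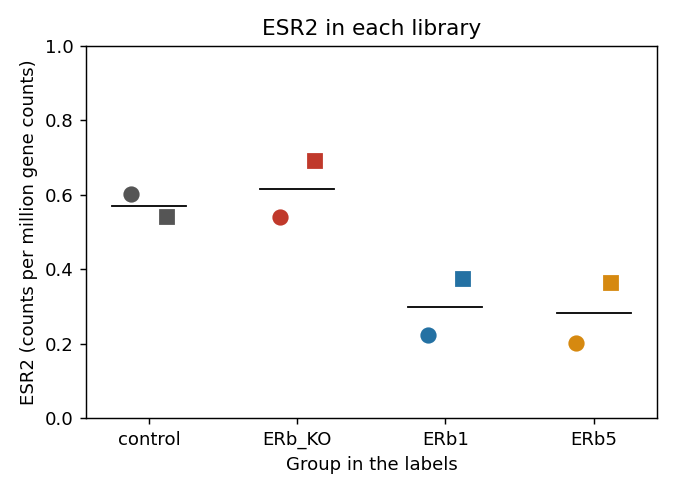
ESR2 in each of the 8 libraries, in CPM of all gene counts (vertical axis), by group in the labels (horizontal axis). Circles are replicate 1, squares replicate 2 and lines group means, and all values lie between 0.203 and 0.69.

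Genes of luminal epithelium were among the most abundant transcripts in all 8 libraries, while most mesenchymal genes typical of glioblastoma lines were near 0. The genes given here were chosen after their values were seen. The keratins KRT8 and KRT18 ran from 2100 to 4430 and from 1690 to 3250 CPM over the libraries. The adhesion genes CDH1 and EPCAM ran from 1730 to 2630 and from 513 to 631 CPM, and the luminal transcription factors XBP1 and GATA3 ran from 3400 to 3910 and from 1110 to 1830 CPM. ESR1, which encodes estrogen receptor alpha, ran from 105 to 144 CPM. Of its targets, TFF1 ran from 253 to 466 CPM, GREB1 from 0.23 to 0.459 CPM, and PGR, which was too low to be tested, was at most 0.0657 CPM. VIM, the intermediate filament of mesenchymal cells, ran from 1.83 to 12.3 CPM. The astrocyte filament GFAP ran from 0.0469 to 0.135 CPM and CHI3L1, a marker of mesenchymal glioma, from 0 to 0.12 CPM. Among other genes of glioma cells, OLIG2 had 0 reads in all libraries, but SOX2 was present at 11.3 to 30.1 CPM. POSTN, a matrix protein of mesenchymal cells, had 0 reads in all libraries. The list of luminal breast genes had a median of 263 to 371 CPM over the libraries, against 0.312 to 1.23 CPM for mesenchymal glioma genes. Of the 20 luminal genes, 16 reached 10 CPM in all libraries. Of the 20 mesenchymal glioma genes 2 did, CD44 (46.9 to 63.3 CPM) and LGALS1 (58.2 to 103 CPM). The medians of the prostate, colon, lung and liver lists were at most 2.94, 0.0329, 0.0832 and 0.0481 CPM.

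**Figure D2:**
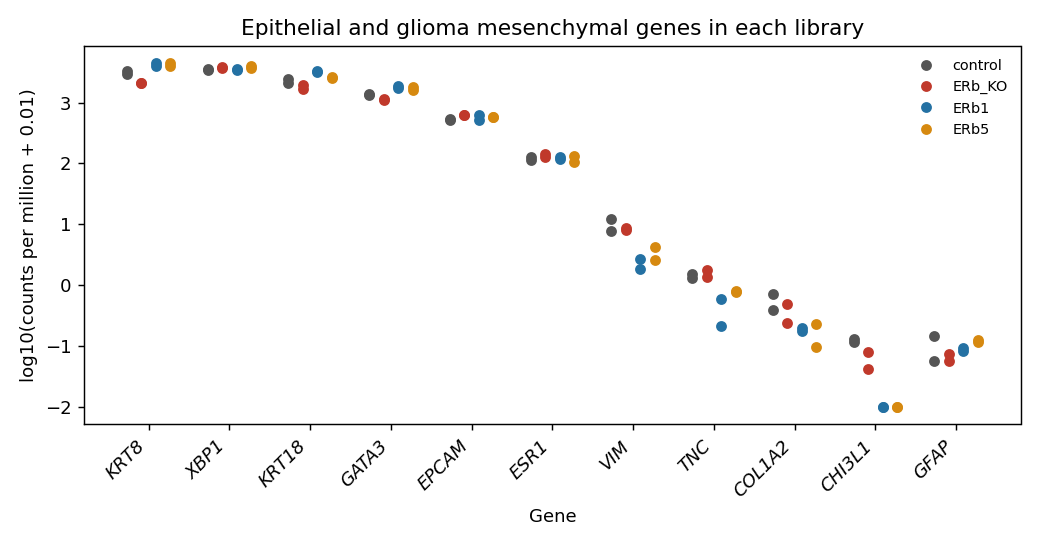
Levels of 11 epithelial, mesenchymal and glial genes (horizontal axis) as log10(CPM + 0.01) (vertical axis), with a point for each library coloured by group. KRT8 lies at 2100 to 4430 CPM and VIM at 1.83 to 12.3 CPM in the 8 libraries.

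Against control, the libraries labelled ERb_KO had much higher levels of interferon-stimulated genes and moderately higher levels of genes for cell division. Chaperones of the endoplasmic reticulum and ribosomal proteins were lower. IFI44L, an interferon-induced gene at 79085587 to 79111830 on chromosome 1, went from 33.4 ± 0.099 to 551 ± 60.4 CPM (SD, n = 2), a log2 change of 4.04 ± 0.17 (SE, edgeR adjusted p = 5.8e-07). Larger rises were seen in XAF1, an interferon-induced promoter of apoptosis (5.24 ± 0.53), in the antiviral gene RSAD2 (4.77 ± 0.46), and in IFIT3 (4.27 ± 0.42) and CMPK2 (4.27 ± 0.43), which also belong to the antiviral response. IFIT1, which binds foreign RNA, rose by 3.65 ± 0.23 and the antiviral sensor enzyme OAS3 by 2.73 ± 0.18. The kinase CDK1, which drives entry into mitosis, rose by 1.06 ± 0.13 and its partner CCNB1 by 0.90 ± 0.11. The DNA untangling enzyme TOP2A rose by 0.99 ± 0.14 and the spindle kinase AURKA by 0.88 ± 0.11. Among the falls, the chaperones PDIA4 (-1.33 ± 0.12), HSP90B1 (-1.17 ± 0.11) and CALR (-1.17 ± 0.14) fold proteins in the endoplasmic reticulum, and CRELD2 (-1.51 ± 0.14) and SDF2L1 (-1.29 ± 0.21) act with them. SPAG4 (-1.64 ± 0.21), the monoamine transporter SLC29A4 (-1.62 ± 0.18), the actin bundler VIL1 (-1.51 ± 0.22), the WNT receptor FZD8 (-1.25 ± 0.14) and the chemokine receptor CXCR4 (-1.25 ± 0.13) also fell.

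Among the interferon genes, 28 of 30 rose and 0 fell (29 rose adjusted over the list alone), with a median log2 change of 2.41 (camera adjusted p = 1.7e-85, and adjusted p = 0.403 with an estimated correlation). Of the mitosis genes, 29 of 30 rose (30 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 3.49e-28, and adjusted p = 0.606 with an estimated correlation). Homologous recombination, which repairs broken DNA, had 19 of 25 genes that rose (20 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 2.64e-13, and adjusted p = 0.606 with an estimated correlation). EME1 (1.02 ± 0.14) and BRIP1 (0.92 ± 0.14) were among them. Genes of antigen presentation rose in 9 of 20 (12 adjusted over the list alone), with a median of 0.93 (camera adjusted p = 9.9e-08, and adjusted p = 0.647 with an estimated correlation). With the GC trend removed 5 of them rose, while the median was 0.95. The peptide transporter TAP2 rose by 1.74 ± 0.21. The ribosomal proteins fell in 35 of 38 (37 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 2.43e-21, and adjusted p = 0.606 with an estimated correlation). RPL13 (-0.84 ± 0.13) is an example, and reads of these genes can be shared with pseudogenes. The share of reads without a single place also differed by group. It was 39.73 and 39.87% in control, 35.43 and 36.43% in ERb_KO, 37.74 and 37.83% in ERb1, and 35.51 and 34.72% in ERb5. Its bearing on the ribosomal list was not tested. In the unfolded protein list, 9 of 20 fell (10 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 5.92e-09, and adjusted p = 0.606 with an estimated correlation).

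Smaller shifts past camera's threshold were rises in the lists for DNA replication (median 0.34), NF-kB (0.44), immediate early genes (0.28) and cholesterol synthesis (0.22), and a fall in nuclear genes of oxidative phosphorylation (-0.20). Their camera adjusted p ran from 1.59e-06 to 0.00795, each with adjusted p = 0.647 with an estimated correlation. The lists of glycolysis (-0.31), NOTCH (-0.35) and antiapoptotic genes (0.38) passed as well (camera adjusted p = 0.00259, 0.0436 and 0.0436, and adjusted p = 0.661, 0.606 and 0.647 with an estimated correlation). Glycolysis lost its call without control 1 or ERb_KO 1 (camera adjusted p = 0.0921 and 0.0989), and the antiapoptotic list without control 1 or ERb_KO 2 (0.0789 and 0.124) and without a filter on low counts (0.0532). NOTCH lost it without control 1, ERb_KO 1 or ERb_KO 2 (camera adjusted p = 0.116, 0.0669 and 0.075), with the replicate number as a block (0.0502) and with the GC trend removed (0.665). That correction gave medians of 0.68 for NF-kB, 0.50 for immediate early genes, -0.18 for glycolysis and 0.24 for antiapoptotic genes. Epithelial markers, of which 2 of 14 fell (4 adjusted over the list alone), had a median of -0.25 (camera adjusted p = 0.0436, and adjusted p = 0.647 with an estimated correlation). That call was lost without control 2 (camera adjusted p = 0.0769), without ERb_KO 1 (0.114) and with the GC trend removed (0.402, median -0.12). Of the replication-dependent histone genes, 0 of 22 changed, with a median of 0.20 (camera adjusted p = 0.338), and with the GC trend removed the list passed (camera adjusted p = 0.00449). Neuronal markers had a median of 0.23, a mean of -0.01 and a camera test pointing down over 6 genes, of which 1 fell (camera adjusted p = 0.951). The membrane estrogen receptor GPER fell by 0.72 ± 0.18 (edgeR adjusted p = 0.0229), but passed in no fit without control 1, control 2, ERb_KO 1 or ERb_KO 2 (edgeR adjusted p = 0.185, 0.0831, 0.0757 and 0.101), nor with the GC trend removed (0.144). ESR1, CDKN1A, CCND1, MYC and EGFR did not pass (edgeR adjusted p from 0.074 to 0.423), although CDKN1A did without a filter on low counts (edgeR adjusted p = 0.039). CCND1 and MYC passed in a fit of these groups only (edgeR adjusted p = 0.0324 and 0.025), and MYC also with the GC trend removed (0.0487). In all, 2434 of 13915 genes changed, 1249 higher and 1185 lower, and 399 of them at least 2-fold. Without control 1, control 2, ERb_KO 1 or ERb_KO 2, 506, 237, 419 and 1480 genes passed, and at least 2-fold 246, 140, 173 and 415.

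The libraries labelled ERb_KO also carried a trend with GC content. Across genes, the log2 level of a library relative to the mean of all libraries correlated with transcript GC content at r = -0.545 and -0.451 in ERb_KO. In the other 6 libraries r was 0.127 and 0.189 in control, 0.343 and -0.135 in ERb1, and 0.115 and 0.329 in ERb5. The ERb1 libraries thus had trends of opposite sign. The median log2 change of ERb_KO against control was 0.342 in the gene decile with the lowest GC content (median 36.8%). It was -0.365 in the decile with the highest (64.1%). Between the same deciles it ran from -0.29 to 0.338 in ERb1 against ERb_KO and from -0.383 to 0.482 in ERb5 against ERb_KO. With each library's trend removed, 1712 genes changed in ERb_KO against control, and 257 of them at least 2-fold. Of the 1712, 1182 were also among the 2434 genes changed without the correction. The medians of the interferon, mitosis and ribosomal protein lists were then 2.38, 0.80 and -0.49.

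**Figure D3:**
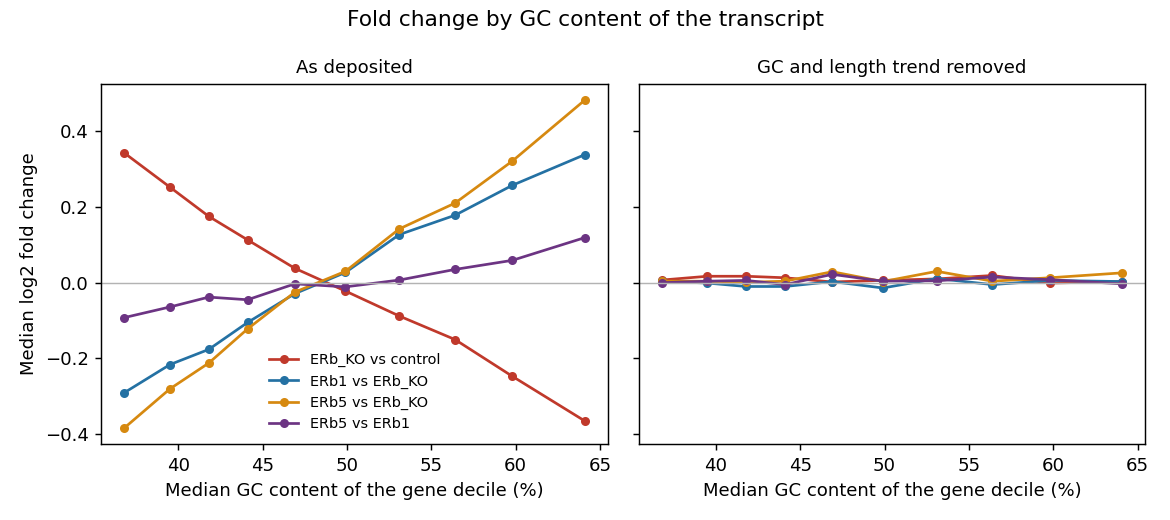
Median log2 fold change of genes in 10 deciles of transcript GC content (vertical axis) against the median GC content of the decile in percent (horizontal axis), for the 4 main comparisons, with counts as deposited (left) and with each library's GC and length trend removed (right). For ERb_KO against control the deposited counts run from 0.342 to -0.365.

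In the libraries labelled ERb1, against those labelled ERb_KO, genes for cell division, DNA replication and repair fell steeply, and interferon and inflammatory genes fell with them. RRM2, which makes deoxynucleotides for DNA synthesis and lies at 10260825 to 10351851 on chromosome 2, went from 236 ± 22.9 to 33.4 ± 1.84 CPM (SD, n = 2), a log2 change of -2.82 ± 0.14 (SE, edgeR adjusted p = 1.91e-06). The kinetochore genes SKA1 (-3.16 ± 0.29), CENPA (-3.14 ± 0.25) and SPC25 (-2.99 ± 0.22), the condensin subunit NCAPG (-2.97 ± 0.22) and the spindle motor KIF2C (-2.77 ± 0.16) fell as well. Interferon genes that fell included RSAD2 (-3.65 ± 0.43), CMPK2 (-3.25 ± 0.40), IFIT3 (-3.11 ± 0.39), HERC5 (-2.98 ± 0.28) and IFI44L (-2.41 ± 0.16). The cytokine genes IL1B (-3.96 ± 0.31), CSF3 (-4.49 ± 0.41), IL8 (-3.17 ± 0.35) and CCL20 (-3.34 ± 0.45) fell from levels of 1.92 to 3.75 CPM. The largest rises among the named genes included HOPX, a homeodomain protein without DNA binding (2.60 ± 0.21, from 1.42 to 8.61 CPM), the growth factor binding protein IGFBP5 (1.80 ± 0.24), CRIP2 (1.72 ± 0.13) and the protease TMPRSS6 (1.68 ± 0.18). The adhesion molecule L1CAM (1.55 ± 0.24), the synuclein SNCG (1.51 ± 0.18) and the tubulin TUBB3 (1.49 ± 0.18) rose as well. GPER rose by 1.48 ± 0.18 (edgeR adjusted p = 0.00025) and the cell cycle gene CCND1 by 0.89 ± 0.12 (edgeR adjusted p = 0.000384).

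All 30 of the mitosis genes fell (30 adjusted over the list alone), with a median log2 change of -1.99 (camera adjusted p = 5.46e-98, and adjusted p = 0.136 with an estimated correlation). Of the DNA replication genes, 24 of 30 fell and 1 rose (25 and 1 adjusted over the list alone), with a median of -0.95 (camera adjusted p = 2.87e-27, and adjusted p = 0.361 with an estimated correlation). Homologous recombination genes fell in 22 of 25 (22 adjusted over the list alone), with a median of -1.23 (camera adjusted p = 1.06e-24, and adjusted p = 0.361 with an estimated correlation). The interferon list had 26 of 30 genes that fell (30 adjusted over the list alone) and a median of -1.76 (camera adjusted p = 3.08e-31, and adjusted p = 0.533 with an estimated correlation). The NF-kB list of inflammatory genes had 14 of 23 that fell (17 adjusted over the list alone) and a median of -1.32 (camera adjusted p = 2.51e-10, and adjusted p = 0.544 with an estimated correlation). Genes that ATF4 turns on for amino acid supply fell in 17 of 25 (18 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 1.79e-07, and adjusted p = 0.544 with an estimated correlation). The cystine transporter SLC7A11 (-1.37 ± 0.14) and the asparagine synthetase ASNS (-0.85 ± 0.12) belong to them. Ribosomal proteins rose in 16 of 38 (25 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 4.42e-06, and adjusted p = 0.744 with an estimated correlation).

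Oxidative phosphorylation rose (median 0.21) and the NRF2 list fell (-0.30), with camera adjusted p = 0.00164 and 0.00292, and adjusted p = 0.544 and 0.798 with an estimated correlation. Antigen presentation (-0.62), EMT genes (5 of 11 fell) and cholesterol synthesis (-0.27) fell too (camera adjusted p = 0.00328, 0.00603 and 0.0234, and adjusted p = 0.85, 0.544 and 0.798 with an estimated correlation). Without ERb1 2 these lists did not pass (camera adjusted p = 0.0517, 0.101 and 0.0517), nor did cholesterol synthesis without ERb_KO 1 (0.0577). Of the epithelial markers, 6 of 14 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.00984, and adjusted p = 0.544 with an estimated correlation). Their call was lost without ERb_KO 1 (camera adjusted p = 0.0539) and with the GC trend removed (0.0933, median 0.04). Histones rose in 4 of 22 and fell in 1, with a median of 0.27 (camera adjusted p = 0.101), and the list passed without ERb_KO 2 (camera adjusted p = 0.0472) and without ERb1 2 (0.0159). Neuronal markers, 1 of 6 higher and 1 lower with a median of -0.27, did not pass (camera adjusted p = 0.917). EGFR fell by 0.60 ± 0.17 (edgeR adjusted p = 0.0239) but lost the call without ERb_KO 1 (edgeR adjusted p = 0.183), ERb1 1 (0.0996) or ERb1 2 (0.0703). ESR1, CDKN1A and MYC did not pass (edgeR adjusted p from 0.406 to 0.767). In ERb1 against ERb_KO, 3466 genes changed, 1720 higher and 1746 lower, of which 711 at least 2-fold, 511 of them lower. Without ERb_KO 1, ERb_KO 2, ERb1 1 or ERb1 2, 1843, 2017, 1198 and 3773 genes passed, and the 2-fold count was 429 without ERb1 1.

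In the libraries labelled ERb5, against those labelled ERb_KO, genes for cell division and DNA replication fell as well, while interferon and antigen presentation genes rose further. RRM2 fell to 53.3 ± 5.33 from 236 ± 22.9 CPM (SD, n = 2), a log2 change of -2.15 ± 0.14 (SE, edgeR adjusted p = 5.83e-05). The complement gene C5 (-2.80 ± 0.22) and CLGN, a chaperone of the endoplasmic reticulum at 141309607 to 141348815 on chromosome 4 (-2.64 ± 0.21), were the largest falls named. SKA1 (-2.32 ± 0.28), the meiotic recombination gene MND1 (-2.23 ± 0.27) and the kinetochore gene NUF2 (-2.07 ± 0.21) fell next. KIF2C (-1.86 ± 0.15), the primase subunit PRIM1 (-1.85 ± 0.16), TOP2A (-1.81 ± 0.14) and CDK1 (-1.54 ± 0.13) fell too. Interferon genes that rose included IFI6 (1.36 ± 0.23), the membrane tether BST2 (1.01 ± 0.13), IFI27 (2.30 ± 0.45) and OASL (1.92 ± 0.40). IFI27 lost its call without ERb_KO 1 or ERb_KO 2 (edgeR adjusted p = 0.0815 and 0.0641), as did OASL (0.0652 and 0.0958), and both did in a fit of these groups only (0.0915 and 0.104). The largest rise among the named genes, HLA-G (5.74 ± 1.4, edgeR adjusted p = 0.0159), belongs to a family with near-identical members. HLA-G lost its call without any 1 of ERb_KO 1, ERb_KO 2, ERb5 1 and ERb5 2 (edgeR adjusted p = 0.143, 0.101, 0.109 and 0.244), with the replicate number as a block (0.0516) and with the GC trend removed (0.0656). GPER rose by 1.30 ± 0.18 (edgeR adjusted p = 0.00112), and CCND1 by 0.52 ± 0.12 (edgeR adjusted p = 0.0092), which did not pass without ERb_KO 2 (0.0657).

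Mitosis genes fell in all 30 (30 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 3.49e-43, and adjusted p = 0.559 with an estimated correlation). Of the DNA replication genes, 21 of 30 fell (21 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 1.52e-17, and adjusted p = 0.559 with an estimated correlation). Homologous recombination genes fell in 20 of 25 (20 adjusted over the list alone), with a median of -0.87 (camera adjusted p = 4.72e-15, and adjusted p = 0.559 with an estimated correlation). The ATF4 list fell in 15 of 25 (19 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 1.76e-11, and adjusted p = 0.559 with an estimated correlation). The serine and folate enzymes MTHFD2 (-1.23 ± 0.15), SHMT2 (-0.77 ± 0.094) and PHGDH (-0.90 ± 0.12) are in this list. The interferon list rose in 25 of 30 (25 adjusted over the list alone), with a median of 1.01 (camera adjusted p = 4.71e-11, and adjusted p = 0.695 with an estimated correlation), and 15 rose with the GC trend removed, with a median of 1.00. Its mean log2 level relative to all libraries was 1.394 in ERb5 1 and 2.351 in ERb5 2, against 1.006 and 0.761 in the ERb_KO libraries. Antigen presentation genes rose in 14 of 20 (16 adjusted over the list alone), with a median of 1.12 (camera adjusted p = 1.75e-07, and adjusted p = 0.695 with an estimated correlation), and 6 rose with the GC trend removed, with a median of 0.99. Their mean relative level was 0.576 in ERb5 1 and 1.753 in ERb5 2, and the peptide loading gene TAPBP rose by 0.64 ± 0.12.

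The NRF2 list rose (median 0.33) and EMT genes (-0.36) and the unfolded protein list (-0.31) fell (camera adjusted p = 0.00156, 0.00999 and 0.0136, and adjusted p = 0.708, 0.695 and 0.713 with an estimated correlation). The EMT call was lost without ERb5 1 (camera adjusted p = 0.0646) and the unfolded protein call without ERb_KO 2 (0.439). Oxidative phosphorylation (0.18), immediate early genes (0.27), NOTCH (0.38) and autophagy (0.16) rose with camera adjusted p = 0.0281, 0.0281, 0.0316 and 0.0325 (adjusted p = 0.695, 0.779, 0.559 and 0.708 with an estimated correlation). Without ERb_KO 1, oxidative phosphorylation, NOTCH and autophagy did not pass (camera adjusted p = 0.103, 0.0541 and 0.116), nor did oxidative phosphorylation, immediate early genes and autophagy without ERb5 2 (0.0703, 0.541 and 0.214) or NOTCH without ERb5 1 (0.066). With the GC trend removed, immediate early genes, NOTCH and autophagy did not pass (camera adjusted p = 0.347, 0.586 and 0.0669), with medians of 0.11, 0.09 and 0.17. Epithelial markers rose in 7 of 14 and fell in 1 (8 and 1 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.00313, and adjusted p = 0.695 with an estimated correlation). Their median was 0.19, with 5 higher and 2 lower, with the GC trend removed. Histones rose in 12 of 22 (13 rose and 1 fell adjusted over the list alone), with a median of 0.62 (camera adjusted p = 0.000289, and adjusted p = 0.695 with an estimated correlation), and did not pass without ERb5 2 (camera adjusted p = 0.0612). The ribosomal protein list did not pass (median -0.11, 2 of 38 fell, camera adjusted p = 0.231), although it passed without ERb_KO 1 (camera adjusted p = 0.00504), and 6 fell with the GC trend removed. Neuronal markers, 1 of 6 higher and 1 lower with a median of -0.17, did not pass either (camera adjusted p = 0.653). ESR1, CDKN1A, MYC and EGFR did not pass (edgeR adjusted p from 0.21 to 0.849), although ESR1 did without ERb5 1 (edgeR adjusted p = 0.0444). In ERb5 against ERb_KO, 3922 genes changed, 2039 higher and 1883 lower, of which 547 at least 2-fold. Without ERb_KO 1, ERb_KO 2, ERb5 1 or ERb5 2, 1859, 1716, 4378 and 1674 genes passed, and the 2-fold count was 336 without ERb5 2. With the GC trend removed the counts were 2540 and 354.

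**Figure D4:**
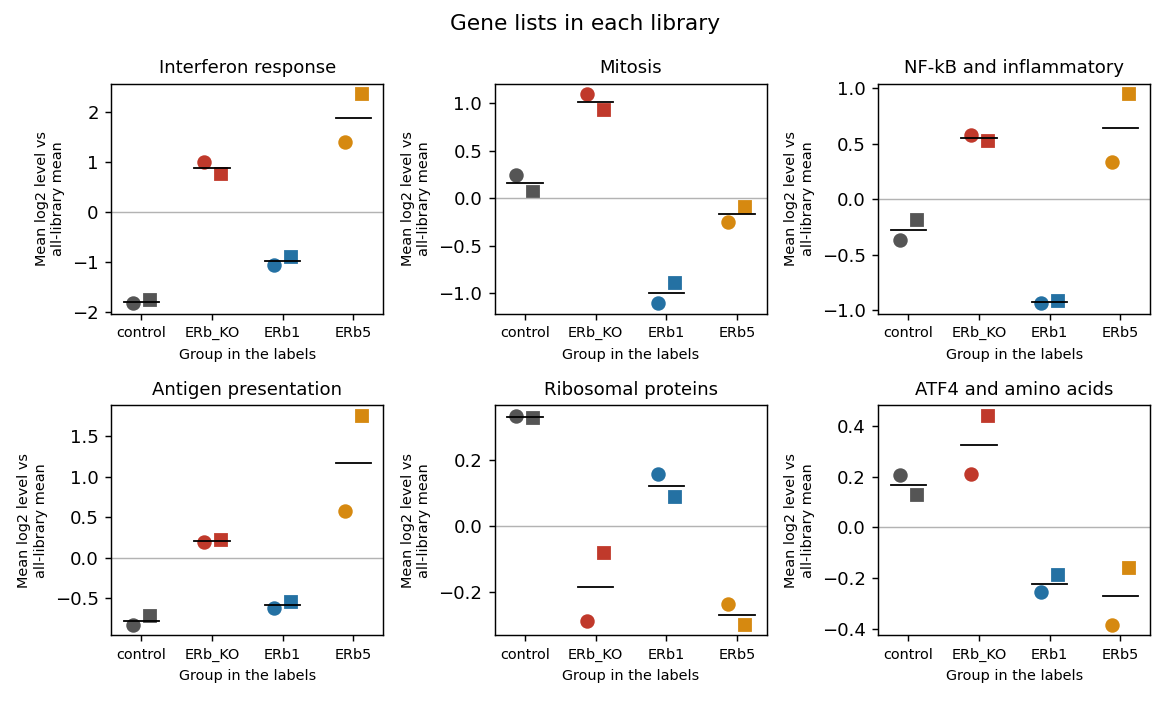
Mean log2 level of the genes of 6 lists relative to the mean of all libraries (vertical axes), in each library by group in the labels (horizontal axes). Circles are replicate 1, squares replicate 2 and lines group means; for the interferon list the ERb_KO libraries lie at 1.006 and 0.761 and the ERb5 libraries at 1.394 and 2.351.

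Between the isoforms, the libraries labelled ERb5 had higher levels of interferon, antigen presentation and inflammatory genes than those labelled ERb1, and also of mitosis genes and some antioxidant genes. HMOX1, a heme-degrading enzyme induced by oxidative stress at 35776354 to 35790207 on chromosome 22, was at 257 ± 111 against 29.6 ± 2.63 CPM (SD, n = 2), a log2 difference of 3.11 ± 0.29 (SE, edgeR adjusted p = 0.00057). RSAD2 was higher by 5.47 ± 0.45, a call lost in a fit of these groups only (edgeR adjusted p = 0.159), HERC5 by 3.41 ± 0.28, IFI44L by 2.64 ± 0.16 and OAS3 by 2.52 ± 0.18. Inflammatory genes that were higher included the chemokine CCL20 (4.56 ± 0.42), IL8 (3.05 ± 0.35), the NF-kB inhibitor TNFAIP3 (2.31 ± 0.23) and the adhesion molecule ICAM1 (1.40 ± 0.15). TAP2 was higher by 2.11 ± 0.21 and the thioredoxin reductase TXNRD1 by 1.00 ± 0.11. AKR1C1 and AKR1C2, reductases with near-identical sequences, were higher by 3.66 ± 0.33 and 3.52 ± 0.31. The mitotic genes KIF20A (1.33 ± 0.17), CDC20 (1.26 ± 0.15), PTTG1 (1.18 ± 0.15) and BIRC5 (1.08 ± 0.13) were higher as well. Lower in ERb5 were IGFBP5 (-1.85 ± 0.24), HOPX (-1.59 ± 0.19) and the iron regulator ACO1 (-1.82 ± 0.28). ACO1 lost its call without ERb1 1 or ERb1 2 (edgeR adjusted p = 0.0758 and 0.0835) and in a fit of these groups only (0.203). SAA1, an acute phase gene with the close copy SAA2, had the largest difference among the named genes (5.97 ± 0.91, edgeR adjusted p = 0.00621) and lost its call without ERb1 1 or ERb1 2 (0.0828 and 0.142) and in a fit of these groups only (0.288).

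The interferon list was higher in all 30 genes (30 adjusted over the list alone), with a median of 2.64 (camera adjusted p = 1.88e-143, and adjusted p = 0.179 with an estimated correlation). Mitosis genes were higher in 25 of 30 (30 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 1.04e-36, and adjusted p = 0.253 with an estimated correlation). Antigen presentation was higher in 16 of 20 genes (19 adjusted over the list alone), with a median of 1.83 (camera adjusted p = 3e-33, and adjusted p = 0.336 with an estimated correlation). The NF-kB list was higher in 14 of 23 (18 adjusted over the list alone), with a median of 1.57 (camera adjusted p = 4.66e-28, and adjusted p = 0.253 with an estimated correlation). Of the antioxidant genes under NRF2, 9 of 22 were higher (15 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 1.69e-21, and adjusted p = 0.336 with an estimated correlation), and 14 were with the GC trend removed. The ribosomal proteins were lower in 14 of 38 (31 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 6.13e-21, and adjusted p = 0.429 with an estimated correlation). Histones, with 1 of 22 higher (1 adjusted over the list alone) and a median of 0.33 (camera adjusted p = 0.0274, and adjusted p = 0.758 with an estimated correlation), did not pass without ERb1 2 (camera adjusted p = 0.69), nor without ERb5 2, where the median was 0.04 and the test pointed down (0.799). Epithelial markers (2 of 14 higher, median 0.03, camera adjusted p = 0.8) did not pass, nor did neuronal markers, whose median of 0.06 and mean of -0.03 had opposite signs (0 of 6 changed, camera adjusted p = 0.68, direction down).

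Other lists past camera's threshold included homologous recombination (median 0.44), DNA replication (0.20), autophagy (0.25), cholesterol synthesis (0.19) and immediate early genes (0.22), all higher, and the unfolded protein list (-0.30), which was lower. The camera adjusted p of these lists ran from 7.29e-05 to 0.00959, and adjusted p from 0.571 to 0.754 with an estimated correlation. Without ERb5 1, homologous recombination and DNA replication did not pass (camera adjusted p = 0.111 and 0.118), and without ERb5 2, cholesterol synthesis and immediate early genes did not (0.593 and 0.798). Immediate early genes did not pass without ERb1 2 (camera adjusted p = 0.151). ESR1, GPER, CDKN1A, CCND1, MYC and EGFR did not pass between ERb5 and ERb1 (edgeR adjusted p from 0.108 to 0.957). CCND1 was lower without a filter on low counts (edgeR adjusted p = 0.0183), without ERb5 1 (0.0141) and with the GC trend removed (0.0484), and CDKN1A without the filter (0.0138). In all, 649 genes differed, 485 higher and 164 lower in ERb5, of which 297 at least 2-fold, 279 of them higher. Without ERb1 1, ERb1 2, ERb5 1 or ERb5 2, 125, 175, 1389 and 298 genes passed, and at least 2-fold 98, 118, 464 and 178. With all libraries, 1112 genes passed with the GC trend removed and 1375 without a filter on low counts.

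The number of lists past camera's threshold was 15 of 41 for ERb_KO against control, 13 for ERb1 against ERb_KO, 15 for ERb5 against ERb_KO and 14 for ERb5 against ERb1. With an estimated correlation, camera called 0 lists in each of the 4 comparisons, and 2, 3, 2 and 5 lists had an unadjusted p under 0.05. The directional fry test, which does not compare a list with other genes, called 5, 15, 10 and 0 lists, with 16, 18, 15 and 14 at an unadjusted p under 0.05, and the fry test for change in either direction called 39, 39, 38 and 34.

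**Figure D5:**
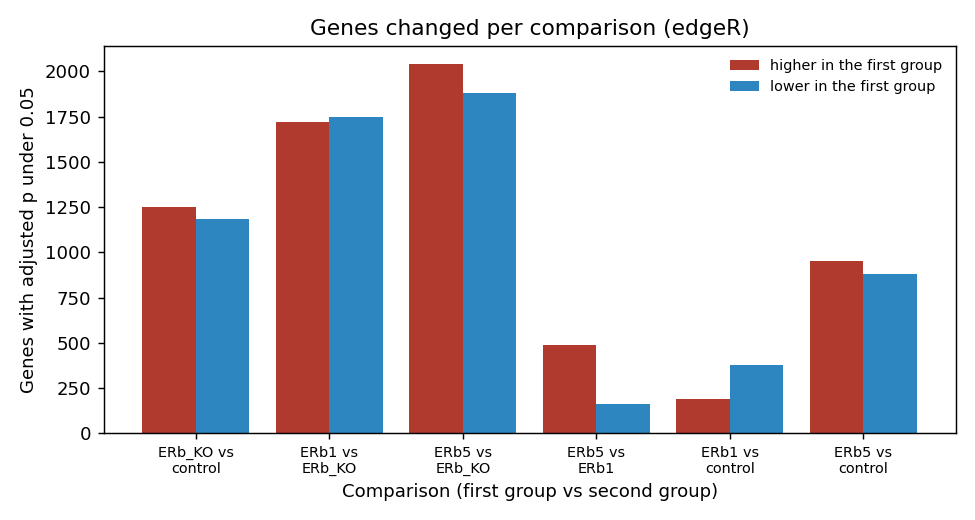
Number of genes with an edgeR adjusted p under 0.05 (vertical axis) in 6 comparisons (horizontal axis), higher or lower in the first group named. The bars run from 164 genes lower in ERb5 against ERb1 to 2039 genes higher in ERb5 against ERb_KO.

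Many genes that differed between the libraries labelled ERb_KO and control moved the other way in the libraries labelled with an isoform. Some moved past control or stopped short of it. Mean relative levels of mitosis genes were 0.246 and 0.069 in control, 1.096 and 0.925 in ERb_KO, and -1.106 and -0.89 in ERb1. For interferon genes they were -1.816 and -1.751 in control, 1.006 and 0.761 in ERb_KO, and -1.058 and -0.886 in ERb1. The unfolded protein list, lower in ERb_KO, did not move back as a whole. Its levels were 0.448 and 0.433 in control and -0.226 and 0.122 in ERb_KO. They were -0.086 and -0.089 in ERb1, and -0.277 and -0.326 in ERb5. In ERb1 against ERb_KO 4 of its 20 genes rose and 2 fell, with a median of -0.08 (camera adjusted p = 0.995). Of the 2434 genes, 1533 (63%) changed in the opposite direction in ERb1 against ERb_KO and 6 changed further in the same direction, where independent lists would share 303.2 and 303.1. For ERb5 the numbers were 1182 (48.6%) and 156, where independent lists would share 342.6 and 343.4. Both counts rest on the same ERb_KO libraries, and sharing them by itself sets the changes against each other. Across genes, the changes of ERb_KO against control and of ERb1 against ERb_KO correlated at r = -0.703, against -0.501 on average (-0.526 to -0.479) in simulated libraries without any effect. For ERb5, r was -0.296 against -0.494 simulated (-0.524 to -0.466). The covariances were -0.2025 and -0.0763, against -0.0248 (-0.0268 to -0.023) and -0.0249 (-0.0271 to -0.0224) simulated. A shift of the ERb_KO libraries alone, absent from the simulated libraries, would also make both covariances more negative. In these simulated libraries 0.02 genes returned in ERb1 and 0.08 in ERb5 on average, but only 0.8 passed in ERb_KO against control, so few could return. Against control, 565 genes differed in ERb1, 189 higher and 376 lower, and 1831 in ERb5, 953 higher and 878 lower. Of the 2434 genes, 112 in ERb1 and 632 in ERb5 still differed from control in the direction of ERb_KO. Another 135 and 72 differed from control in the opposite direction. The other 2187 in ERb1 and 1730 in ERb5 did not differ from control, which does not show that their levels were equal. Without control 1, control 2, ERb_KO 1, ERb_KO 2 or ERb1 1, the ERb1 count was 418, 185, 314, 917 and 782, and the ERb5 count was 252, 93, 194 and 601 without the first 4 of these. The count against control for ERb1 was 128, 232, 235 and 217 without control 1, control 2, ERb1 1 and ERb1 2, and for ERb5 587, 732 and 1081 without control 1, control 2 and ERb5 2. With the GC trend removed, 1283 genes in ERb1 and 2842 in ERb5 differed from control. Of the 1712 genes then changed in ERb_KO against control, 1081 (63.1%) moved back in ERb1 and 596 (34.8%) in ERb5.

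Across genes, the log2 changes of ERb1 and ERb5 against ERb_KO correlated at r = 0.589 (genes are not independent replicates), where simulated libraries without any effect, sharing the ERb_KO libraries, gave 0.489 on average (0.465 to 0.512). The covariance was 0.174 against 0.0248 simulated, a difference of 0.149. With ERb1 set against ERb_KO 1 and ERb5 against ERb_KO 2, or the other way round, r was 0.459 and 0.511. These 2 values use differences of log2 CPM in place of fitted changes. No simulated value was made for this split, and 0.489 is not its reference because it holds for shared ERb_KO libraries. A shift of the ERb_KO libraries alone, such as their GC trend, enters both changes and is absent from the simulated libraries. It would raise the covariance without any isoform effect, and splitting the ERb_KO libraries does not remove a shift that both share. Both isoforms had 1064 genes higher and 1060 lower, where independent lists would share 252 and 236.3. The simulated libraries, without any effect, shared 0.08 on average. Few genes pass in such libraries (0.8 on average in ERb_KO against control), so few could be shared, and part of the excess can come from the shared libraries. Another 89 genes, the chemokine gene CCL20 among them, were lower in ERb1 and higher in ERb5, and 0 genes went the other way, where independent lists would share 255.8 and 232.8. The 89 genes became 24, 11, 24, 41, 204 and 48 without ERb_KO 1, ERb_KO 2, ERb1 1, ERb1 2, ERb5 1 and ERb5 2, and without ERb5 1, 24 genes went the other way. The shared rises fell to 443, 498, 406 and 644 and the shared falls to 579, 528 and 525 without the libraries that moved them by more than 1.5 times, which were ERb_KO 1, ERb_KO 2, ERb1 1 and, for the rises, ERb5 2. With the GC trend removed, 620 rises and 870 falls were shared, 60 genes were lower in ERb1 and higher in ERb5, and 4 went the other way.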

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

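The GC correction is the only test in this part that was chosen after its result could be seen. Set against the libraries labelled ERb_KO, the libraries labelled ERb1 and ERb5 moved some genes in opposite directions, and each difference given here was tested directly between ERb5 and ERb1. In all, 89 genes were lower in ERb1 and higher in ERb5, where independent lists would share 255.8. All 89 also differed between ERb5 and ERb1. Genes called on opposite sides of the same libraries almost always do, so the direct test adds little for these genes. RSAD2 (-3.65 and 1.82) is among them, and its rise in ERb5 did not pass without ERb_KO 1 or ERb_KO 2 (edgeR adjusted p = 0.0672 and 0.095). In fits of only the groups compared, that rise and the difference between ERb5 and ERb1 did not pass for RSAD2 (edgeR adjusted p = 0.0966 and 0.159). The number lower in ERb1 and higher in ERb5 was 24, 11, 24, 41, 204 and 48 without ERb_KO 1, ERb_KO 2, ERb1 1, ERb1 2, ERb5 1 and ERb5 2, and 60 with the GC trend removed. The interferon list had a median log2 change of -1.76 in ERb1 and 1.01 in ERb5 (camera adjusted p = 3.08e-31 and 4.71e-11, and adjusted p = 0.533 and 0.695 with an estimated correlation), with a median of 2.64 between them (camera adjusted p = 1.88e-143, and adjusted p = 0.179 with an estimated correlation). Antigen presentation moved by -0.62 and 1.12 (camera adjusted p = 0.00328 and 1.75e-07, and adjusted p = 0.85 and 0.695 with an estimated correlation), and by 1.83 between them (camera adjusted p = 3e-33, and adjusted p = 0.336 with an estimated correlation), where the fall in ERb1 did not pass without ERb1 2 (0.0517). The NRF2 list moved by -0.30 and 0.33 (camera adjusted p = 0.00292 and 0.00156, and adjusted p = 0.798 and 0.708 with an estimated correlation), and by 0.39 between them (camera adjusted p = 1.69e-21, and adjusted p = 0.336 with an estimated correlation). Its mean relative level was higher in ERb5 2 (0.687) than in ERb5 1 (0.283), against 0.011 and 0.141 in ERb_KO and -0.451 and -0.4 in ERb1. The directional fry test passed for the interferon fall in ERb1 (fry adjusted p = 0.0266), but not for the interferon rise in ERb5 (0.141) or the difference between them (0.0603), nor for the other 2 lists in any of these comparisons (0.0642 to 0.249). Because the ESR2 counts do not bear out the isoform labels, these are differences between libraries labelled ERb1 and ERb5, and no explanation of them was tested.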

How the results depend on the processing

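The GC correction was added after the data were seen. Over all alternatives, the named genes' calls stayed the same in 2613 instances, were lost in 199 and gained in 16, and 0 reversed. For the called lists and those of other cell types and RNA quality, 512 calls stayed the same, 133 were lost, 4 were gained and 1 reversed. The reversed call was that of the histones in ERb5 against ERb1, with a median of 0.33 that ranged from 0.04 to 0.56 when a library was left out, and a test pointing down without ERb5 2. The size factors (relative log expression, upper quartile) changed no call of a named gene, and the cause was not tested for any change given here unless it is stated.

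Leaving out a library, which lowers the residual degrees of freedom, gave 237 to 1480 changed genes (140 to 415 at least 2-fold) for ERb_KO against control, 1198 to 3773 (429 to 831) for ERb1 against ERb_KO, 1674 to 4378 (336 to 799) for ERb5 against ERb_KO and 125 to 1389 (98 to 464) for ERb5 against ERb1. Against control it gave 128 to 235 (95 to 160) for ERb1 and 587 to 2143 (343 to 659) for ERb5. Genes returned toward control numbered 185 to 1882 for ERb1 and 93 to 1440 for ERb5. The correlation of the isoforms' changes ran from 0.418 to 0.653. In differences of log2 CPM it was 0.459 with ERb1 against ERb_KO 1 and ERb5 against ERb_KO 2.

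A test against a minimum change of 1.5-fold, stricter by construction, left 123 genes in ERb_KO against control, 455 in ERb1 and 160 in ERb5 against ERb_KO, 189 in ERb5 against ERb1, and 86 in ERb1 and 341 in ERb5 against control. A fit with only the groups compared gave 4351 genes in ERb_KO against control, 421 in ERb5 against ERb1 and 1107 in ERb1 against control. Without a filter on low counts, 1375 genes differed between ERb5 and ERb1 and 1384 between ERb1 and control (327 at least 2-fold), and 1914 returned toward control in ERb5. DESeq2 gave 851 for ERb1 against control. Camera with an estimated correlation called 0 lists in ERb_KO against control, 0 in ERb1 against ERb_KO, 0 in ERb5 against ERb_KO and 0 in ERb5 against ERb1 (2, 3, 2 and 5 at an unadjusted p under 0.05). The directional fry test called 5 lists in ERb_KO against control and 0 in ERb5 against ERb1 (16 and 14 at an unadjusted p under 0.05). With the GC trend removed, the numbers were 257 at least 2-fold for ERb_KO against control, 2540 (354 at least 2-fold) for ERb5 against ERb_KO, 1112 for ERb5 against ERb1, 1283 for ERb1 and 2842 for ERb5 against control, and 596 returned in ERb5.

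Replicate numbers gave no sign of pairing libraries between groups (r of the replicate differences from -0.12 to 0.139 across genes, which are not independent replicates). With 2 libraries per group, a low r does not exclude that replicate numbers pair them. With the number as a block, 2532, 3519, 3929, 652, 581 and 1850 genes changed in the 6 comparisons, and 1 named gene (HLA-G in ERb5 against ERb_KO, edgeR adjusted p = 0.0516) and 1 list (NOTCH in ERb_KO against control, camera adjusted p = 0.0502) lost their call. Depth limits what can be said of ESR2 (6 to 25 reads) and of the genes under 1 CPM.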

Other observations

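The tests of the source of the RNA, of a library swap and of a missing transcript of the isoform were chosen after their results had been seen, and the GC correction was also added then. Some mesenchymal genes that are scarce in these libraries were lower in the libraries labelled ERb1 and ERb5 than in those labelled ERb_KO. The genes were chosen after their values were seen. The fixed list of mesenchymal glioblastoma genes did not pass, and had 7 of 23 that fell and 3 that rose in ERb1 (9 and 4 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.301). In ERb5, 6 fell and 5 rose (10 and 8 adjusted over the list alone), where the median of 0.22 and the mean of -0.29 had opposite signs and the test pointed down (camera adjusted p = 0.616). Against ERb_KO, the filament VIM fell by 1.90 ± 0.30 in ERb1 and 1.26 ± 0.28 in ERb5 (edgeR adjusted p = 0.00125 and 0.0102), and the membrane protein ANXA1 by 1.68 ± 0.25 and 1.83 ± 0.26 (0.000893 and 0.00119). The matrix protease MMP2 changed by -1.50 ± 0.36 and -2.18 ± 0.40 (edgeR adjusted p = 0.0121 and 0.00414). Leaving out a library ended the calls of MMP2 in ERb1 (edgeR adjusted p = 0.0526, 0.0779 and 0.055 without ERb_KO 1, ERb1 1 and ERb1 2) and VIM in ERb5 (0.0508 without ERb_KO 2). The matrix protein TNC fell in ERb1 (-2.07 ± 0.41, edgeR adjusted p = 0.00431) and did not pass in ERb5 (-0.98 ± 0.37, 0.0651), except without a filter on low counts (0.0142). Between ERb5 and ERb1 it did not pass (edgeR adjusted p = 0.221). AXL did not pass in either, and NES passed only in ERb5 without that filter (edgeR adjusted p = 0.0277). The EMT list, which holds VIM and AXL, passed in both (camera adjusted p = 0.00603 and 0.00999, and adjusted p = 0.544 and 0.695 with an estimated correlation), but not without ERb1 2 in ERb1 (0.101) or ERb5 1 in ERb5 (0.0646). Epithelial markers rose in 6 of 14 and in 7 of 14, with 1 lower in each. With the GC trend removed, 6 rose and 3 fell in ERb1 (median 0.04), and 5 rose and 2 fell in ERb5 (median 0.19). In ERb_KO against control, VIM, ANXA1, MMP2 and TNC did not pass (edgeR adjusted p = 0.452, 0.855, 0.936 and 0.865). Against control, ERb1 and ERb5 were lower in VIM (-2.20 and -1.55), ANXA1 (-1.75 and -1.89) and MMP2 (-1.54 and -2.23). TNC passed against control in ERb1 only (edgeR adjusted p = 0.0196, and 0.139 in ERb5). The falls of these genes are therefore not a return toward control.

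All libraries carried luminal epithelial genes at high levels, with FOXA1 at 336 to 438 CPM and KRT8 at 2100 to 4430 CPM, and near-absent mesenchymal glioma genes, apart from CD44 (46.9 to 63.3 CPM) and LGALS1 (58.2 to 103 CPM). A minor share of epithelial cells or reads mixed into glioblastoma cells would leave the mesenchymal list above the luminal list, yet the luminal median was at least 276 times the mesenchymal median in every library. Gene symbols shifted against their counts would scatter the ribosomal proteins, yet 37 of 38 stood above 20 CPM in every library. A candidate explanation is that the RNA came from luminal epithelial cells and not from the line in the labels, and in 8 of 8 libraries the luminal list had the highest median of the 6 lineage lists, which do not share genes. No genotype of the cells was compared with the line here, an altered state of the line was not tested, and the list was written after some levels were seen, so this remains a hypothesis.

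ESR2 was not higher in the libraries labelled ERb1 and ERb5 than in those labelled ERb_KO. Reads lost to an overlapping gene are argued against by 0 percent of the ESR2 coding bases lying in exons of other genes, and reads lost to shared sequences by 0 percent of the 1541 windows of 50 bases occurring in transcripts of other genes. A swap of an isoform library with a library of another group would leave a high ESR2 level in another group if the construct is counted as ESR2, and the highest of any library was 0.69 CPM. That the isoform was not transcribed in the cells sequenced could give the highest level of 0.374 CPM in ERb1 and ERb5. Neither can be told apart from a construct whose sequence differs from the reference and is not counted, since the construct is not described in the sources used here, and no biological explanation was tested.

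The GC trend of the ERb_KO libraries could produce changes against control that seem to return in the isoform libraries, which share the ERb_KO libraries as reference. With the trend removed, the counts of returned genes were 0.705 of the uncorrected count for ERb1 and 0.504 for ERb5, so how many genes returned cannot be told apart from the trend for part of them. Fewer genes were then changed in ERb_KO against control, 1712 against 2434. The share of them that returned was 63.1% against 63% uncorrected for ERb1, and 34.8% against 48.6% for ERb5. Of the 1533 and 1182 returned genes, 731 and 388 also returned after the correction. The medians against control were 0.988 of the uncorrected value for the interferon list, 0.964 for mitosis and 0.98 for ribosomal proteins, which argues against the trend as the whole cause of these shifts. A difference in the ERb_KO cells themselves stays open.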
